A study of Mus musculus with 7 samples.

How the data were processed

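RNA from the duodenum of 7 male mice was sequenced. The strain is C57BL/6 in the sample labels and C57BL/6J in the series description, and the length of treatment is not given in the sources used here. The mice were aged 8 to 12 weeks, 4 given vehicle (0.5% carboxymethylcellulose) and 3 given T09 at 50 mg/kg/day, with 1 library per mouse. T09 is T0901317, an agonist of the liver X receptors (LXR), nuclear receptors that sense oxysterols. Per the labels' protocols, polyadenylated RNA was purified and libraries were made with a kit that uses random priming. The submitters' processing notes name TopHat2 2.0.12, Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq 1.18.0, without roles or order. The genome build, the annotation and the handling of strand and of reads shared by several genes are not given in the sources used here. Values of antisense or overlapping genes and of members of near-identical families are therefore uncertain.

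The deposited table holds raw read counts per Ensembl gene in 7 columns, per the file headers, and FPKM in a further 7 columns, which the authors computed from the counts. The FPKM values were checked against the counts and not used in any test. Among genes with over 50 counts, 24.0% to 24.5% per library had the FPKM expected from count, listed length and total within 0.1%. The table has 47069 genes. Of these, 46515 overlap their gene in GENCODE M21 on the same chromosome and 39771 have exactly its coordinates, so coordinates are given on GRCm38. The table had no usable name for 24557 genes, of which 24253 were named by their identifier from M21. Counts summed to between 15395535 and 20494485 per library. Every count column was matched to 1 library by its title.

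Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the treatment groups, libraries were scaled by TMM, and T09 was compared with vehicle by the quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over the 14250 genes kept. A gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Values per library are CPM, computed from the deposited counts with TMM-scaled library sizes. On simulated counts drawn from these libraries' means and dispersions, with 200 of 14250 genes changed in each of 5 draws, the test recovered 17.2% of genes changed by 1.5-fold, 48.8% at 2-fold, 84.4% at 4-fold and 94.4% at 8-fold. None was called in the wrong direction, and 8.79% of all calls were genes simulated without change.

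Gene lists for the treatment, for pathways and for the cell types a duodenal sample can hold were fixed before the data were examined, 36 in number, and 35 had at least 3 genes tested. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated per list and with fry. On counts simulated with LXR targets raised 2-fold, camera called that list and also 1 list sharing no gene with it. For each list, the number of the 35 splits of the 7 libraries into 4 and 3 with a camera p at least as small was also counted. That count was added after the number of lists called on other splits had been seen. The share of each library's counts in 6 marker lists was compared by an exact permutation test, two-sided, of mean log2 shares over the 35 splits. The smallest p this design allows is 0.0286. The share of the adipocyte list was added after the data were examined.

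Genes are named by a rule fixed before the data were examined. It takes the 8 largest changes in each direction among called genes with a mean of at least 1 CPM, groups that do not overlap and a named symbol. It also takes 10 index genes of LXR action and sterol transport, up to 4 genes of each list called, up to 2 of another list described, and the 4 smallest adjusted p. Of the genes that this rule names, 1 is not reported here. Scd1, Fasn, Ppara, Nqo1, Gclc, Akp3 and Ada are named in addition, chosen after their values were seen.

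Alternatives were DESeq2's size factors, library size alone, scaling without the 20 most abundant genes and 3 lists, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in at least 3 libraries, a test against 1.5-fold, 1 surrogate variable (sva 3.50.0), the replicate number as a block, and leaving out each library in turn. Added after the data were examined were the smooth muscle score (mean log2 CPM of its list, prior count 2) as a covariate and the removal of both libraries numbered 1. A trend with GC content and transcript length was removed per library by loess with a span of 0.3 in 1 test. Shares and permutation tests were computed in Python 3.11.15.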

Results

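Duodenal RNA of 4 vehicle-treated and 3 T09-treated mice was compared to ask how an LXR agonist changes the intestinal transcriptome. The vehicle libraries held 19007647, 18944222, 15395535 and 18351441 counts, and the T09 libraries 20494485, 18592414 and 18040531. Between 19014 and 19930 genes had at least 1 count in a library, and 14250 were tested.

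With T09, the lists of LXR targets and of PPAR alpha targets rose, with 11 of 20 and 11 of 21 tested genes higher (camera with an estimated correlation, adjusted p = 6.92e-04 and 0.0403). Of PXR and CAR targets 11 of 20 genes were higher, and of smooth muscle and enteric neuron genes 11 of 12 and 5 of 10 were lower. These 3 lists were not called with an estimated correlation (camera adjusted p = 0.0752 each), but were called with fry (adjusted p = 0.0103, 0.0103 and 0.00587). By edgeR's quasi-likelihood test, 614 of 14250 genes changed at an adjusted p under 0.05, of which 205 were higher and 409 lower. Changes over 2-fold were seen for 83 of the higher and 338 of the lower genes. All 614 had groups that did not overlap, a state reached by 2388 of the genes tested (16.8%, against 5.71% by chance).

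Among LXR targets, 11 of 20 tested genes were higher and 0 lower (12 higher adjusted over the list alone). Srebf1, which encodes the lipogenic transcription factor SREBP-1, was 8.23-fold higher with T09, at 1193 ± 70.2 CPM (SD, n = 3) against 145 ± 25.8 CPM (SD, n = 4). Its log2 fold change was 3.04 (SE 0.15, edgeR adjusted p 3.97e-05). Scd2, a stearoyl-CoA desaturase, went from 17.2 ± 5.42 to 496 ± 98.1 CPM (log2 fold change 4.85, SE 0.25). The cholesterol efflux transporters Abca1 and Abcg1 were higher by 2.41 (SE 0.17) and 3.43 (SE 0.33) on the log2 scale. Mylip, the ubiquitin ligase that acts on the LDL receptor, was higher by 3.05 (SE 0.16). The sterol exporters Abcg5 and Abcg8 were higher by 1.08 (SE 0.11) and 0.93 (SE 0.11), and the phospholipid-remodelling enzyme Lpcat3 by 0.81 (SE 0.09). These 8 genes had edgeR adjusted p between 3.97e-05 and 0.00313. The receptors themselves were not called: Nr1h3 (LXR alpha) had a log2 fold change of 0.19 (SE 0.15) and Nr1h2 (LXR beta) of -0.04 (SE 0.10). Npc1l1, the cholesterol uptake transporter, had a log2 fold change of -0.57 (SE 0.15, edgeR adjusted p 0.0680) and did not pass. As a list, LXR targets rose with camera (adjusted p 1.90e-44) and with an estimated correlation (adjusted p 6.92e-04).

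**Figure D1:**
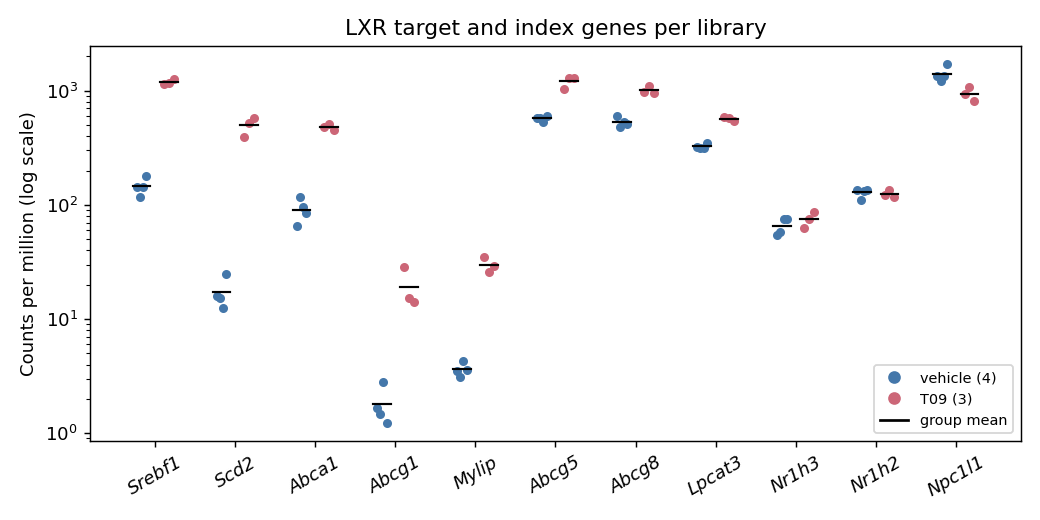
CPM on a log axis for 11 LXR target and index genes, 1 point per library, 4 vehicle and 3 T09, with lines at group means. Srebf1 lies at 145 ± 25.8 CPM (mean ± SD) with vehicle and 1193 ± 70.2 CPM with T09, whereas Nr1h2 lies at 128 ± 11.6 and 125 ± 8.75 CPM.

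On GRCm38, the genes with the smallest adjusted p lie as follows. Srebf1 (ENSMUSG00000020538) is on chromosome 11, 60199089 to 60222581. Scd2 (ENSMUSG00000025203) is on chromosome 19, 44293676 to 44306864, Mylip (ENSMUSG00000038175) on chromosome 13, 45389742 to 45412019 and Akr1b8 (ENSMUSG00000029762) on chromosome 6, 34354119 to 34368463. Their counts are totals over each gene.

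Of the fatty acid synthesis list, 7 of 21 tested genes were higher and 0 lower (8 higher adjusted over the list alone). Besides Srebf1 and Scd2, they included malic enzyme Me1 (log2 fold change 2.24, SE 0.20) and Mid1ip1 (log2 fold change 1.15, SE 0.14). The list's median log2 fold change was 0.27 (0.11 to 0.28 when each library was left out in turn). Its camera call (adjusted p 8.33e-16) did not hold with an estimated correlation (adjusted p = 0.0786), but fry called the list (adjusted p = 0.0103). Scd1, chosen after its values were seen, lay at 144 ± 240.1 CPM (SD, n = 4) with vehicle and 3694 ± 1054 CPM (SD, n = 3) with T09, and was not called (edgeR adjusted p 0.0735). Vehicle replicate 4 alone held 503 CPM of it. Without that library the log2 fold change went from 4.68 (SE 1.25) to 7.23 (SE 0.77, edgeR adjusted p 0.00629). Over its alternatives adjusted p ranged from 0.00138 to 0.762, the latter with the smooth muscle covariate, where no gene was called. On all 7 libraries Scd1 was called by DESeq2 (adjusted p 0.00856) and limma-voom (adjusted p 0.0179). EdgeR called it with no filter (adjusted p 0.0151) and 1 surrogate variable (adjusted p 0.0319). It was not called under the other scalings, the stricter filter or the 1.5-fold test. Fasn, chosen likewise, had a log2 fold change of -1.20 (SE 0.71, edgeR adjusted p 0.433) and vehicle replicate 4 at 257 CPM.

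Cholesterol synthesis genes went both ways. Sqle (squalene epoxidase, log2 fold change -1.41, SE 0.21), Cyp51 (lanosterol demethylase, log2 fold change -0.98, SE 0.14) and Mvd (mevalonate decarboxylase, log2 fold change -0.93, SE 0.20) were lower, and the sterol sensor partner Insig1 (log2 fold change 0.58, SE 0.13) was higher; the calls of Mvd and Insig1 were lost without at least 1 of the libraries. These were 3 lower and 1 higher of 25 tested (7 lower and 1 higher adjusted over the list alone). The list's median was -0.18 (-0.29 to -0.13 when each library was left out in turn), and its camera call (adjusted p 0.00421) was lost with an estimated correlation (adjusted p = 0.689).

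Targets of PPAR alpha, the nuclear receptor of fatty acid oxidation, were higher in 11 of 21 tested genes and lower in 0 (16 higher and 1 lower adjusted over the list alone). Cyp4a10, a fatty acid omega-hydroxylase, was 10.5-fold higher (6.66 ± 2.22 to 70.2 ± 13.2 CPM), and the acyl-CoA thioesterase Acot1 8.94-fold. Acot2 (log2 fold change 2.00, SE 0.22) and the peroxisomal thiolase Acaa1b (log2 fold change 1.95, SE 0.15) were also higher. The list rose with camera (adjusted p 4.77e-27) and with an estimated correlation (adjusted p 0.0403). Ppara itself, chosen after its values were seen, was higher by 1.70 (SE 0.12, edgeR adjusted p 2.65e-04).

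Targets of PXR and CAR, the xenobiotic-sensing receptors, were higher in 11 of 20 tested genes and lower in 0 (18 higher adjusted over the list alone). Among them were the epoxide hydrolase Ephx1 (log2 fold change 2.15, SE 0.18), the carboxylesterase Ces2a (log2 fold change 1.71, SE 0.21), Aldh1a1 (log2 fold change 1.57, SE 0.18) and the cytochrome P450 reductase Por (log2 fold change 0.96, SE 0.11). The camera call (adjusted p 9.26e-30) did not hold with an estimated correlation (adjusted p = 0.0752), but fry called the list (adjusted p = 0.0103). Outside the lists, the aldo-keto reductase Akr1b8 had the largest fold change among the higher genes named by rule, 47.2-fold (6.80 ± 3.30 to 320.5 ± 61.2 CPM). Gsta2, a glutathione transferase, was 8.94-fold higher. Akr1b8, Acot1, Acot2, Gsta2, Cyp4a10, Ces2a and Scd2 have close relatives, and reads shared between copies leave their single values uncertain. The same holds for the immunoglobulin segment Ighv1-74 (log2 fold change 4.10, SE 0.50), with 238 counts in T09 replicate 1 and 78 and 89 in the other T09 libraries.

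Of genes for lipid uptake and chylomicron assembly, 4 of 25 were higher and 0 lower (4 higher and 3 lower adjusted over the list alone). The higher genes were the sterol acyltransferase Soat1 (log2 fold change 1.55, SE 0.12), the lipid droplet protein Plin2 (log2 fold change 0.83, SE 0.09) and the fatty acid binding proteins Fabp1 (log2 fold change 0.88, SE 0.16) and Fabp2 (log2 fold change 0.81, SE 0.17). The list's camera call (adjusted p 0.0450) was lost with an estimated correlation (adjusted p = 0.513). Of bile acid handling genes, 1 of 8 was higher (2 adjusted over the list alone), the transporter Abcc2 (log2 fold change 0.66, SE 0.13), and the camera call (adjusted p 0.00591) was lost with an estimated correlation (adjusted p = 0.400). Fabp1, Fabp2 and Abcc2 each lost their call without at least 1 of the libraries. Retinoid metabolism was not called as a list (camera adjusted p 0.397), but 1 of 14 genes was lower, the carotene oxygenase Bco1 (log2 fold change -2.58, SE 0.31), and 2 were higher, including Aldh1a1 (2 higher and 1 lower adjusted over the list alone). In the inflammation and antimicrobial list, 3 of 8 were higher (3 higher and 1 lower adjusted over the list alone), the antimicrobial lectins Reg3a (log2 fold change 1.04, SE 0.16) and Reg3b (log2 fold change 0.76, SE 0.18) and the cytokine Il18 (log2 fold change 0.90, SE 0.16), of which Reg3b and Il18 lost the call without at least 1 library. That list's median was 0.35 (0.17 to 0.75 when each library was left out in turn) and its mean -0.19, and its camera call towards higher values (adjusted p 0.0202) was lost with an estimated correlation (adjusted p = 0.347).

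Smooth muscle genes were lower with T09 in 11 of 12 tested, with none higher (12 lower adjusted over the list alone) and a median log2 fold change of -2.18. Synpo2 fell from 42.1 ± 9.17 to 8.43 ± 1.14 CPM, the actin gene Acta2 from 253 ± 44.6 to 60.2 ± 22.1 CPM, and Des (desmin) from 226 ± 70.3 to 47.3 ± 12.5 CPM. The list took 0.165% ± 0.0397 of counts with vehicle (SD, n = 4) and 0.0368% ± 0.0119 with T09 (SD, n = 3), 4.55-fold less by mean log2 share (exact permutation p = 0.0286, the smallest possible). Over the 6 marker lists tested the adjusted value was 0.171, which does not pass. A single list at the smallest possible p cannot pass this adjustment, so it does not decide. Of enteric neuron and glia genes, 5 of 10 were lower (8 adjusted over the list alone), including Stmn2 (log2 fold change -2.93, SE 0.46), Tubb3 (log2 fold change -2.25, SE 0.37) and Uchl1 (log2 fold change -2.06, SE 0.32). The camera calls of both lists (adjusted p 1.19e-39 and 7.38e-12) did not hold with an estimated correlation (adjusted p = 0.0752 for each). Fry called both lists (adjusted p = 0.0103 and 0.00587).

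The following lower genes stood beside the same difference in smooth muscle share, 0.165% with vehicle and 0.0368% with T09. The largest decreases among called genes named by rule included the mesenchymal homeobox gene Nkx3-2, with 192 counts over the vehicle and 6 over the T09 libraries. The collagen gene Col8a2 had 235 and 12. Others were Sult4a1 (log2 fold change -3.49, SE 0.48), Stmn3 (log2 fold change -3.22, SE 0.76), Gpr85 (log2 fold change -3.20, SE 0.49), the neuropeptide gene Gal (log2 fold change -3.19, SE 0.76), the synaptic gene Syt1 (log2 fold change -3.08, SE 0.43) and the matrix gene Optc (log2 fold change -3.07, SE 0.40). Of immediate early genes, 5 of 14 were lower (6 adjusted over the list alone), among them Fos (log2 fold change -0.98, SE 0.14), Jun (log2 fold change -1.04, SE 0.18), Egr1 (log2 fold change -1.33, SE 0.23) and Fosb (log2 fold change -2.48, SE 0.52). Among these lower genes, Stmn3, Gal, Jun and Fosb lost their call without at least 1 library. The immediate early list's camera call (adjusted p 7.79e-08) was lost with an estimated correlation (adjusted p = 0.142), but fry called the list (adjusted p = 0.0223). No fibroblast and matrix gene of 12 was called (1 lower adjusted over the list alone; median -0.64; adjusted p = 0.712 with an estimated correlation). This rests on T09 replicate 1: without it 8 of 12 were called lower by edgeR (median -1.54). Without that library the medians of endothelial, macrophage and dendritic cell, and B and plasma cell genes also went from 0.22, 0.48 and 1.11 to -0.83, -0.77 and -0.02. No adipocyte gene of 7 was called (5 lower adjusted over the list alone; adjusted p = 0.513 with an estimated correlation). Adipocyte counts stood highest in vehicle replicate 4, at 0.0330% against at most 0.00568% in the other vehicle libraries.

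**Figure D2:**
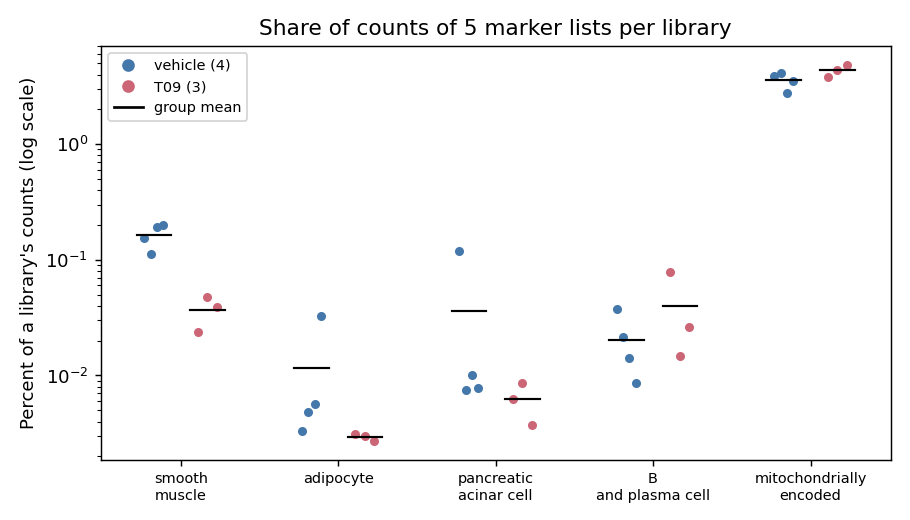
Percent of each library's counts in 5 marker lists, on a log axis, 1 point per library, 4 vehicle and 3 T09, with lines at group means. Smooth muscle takes 0.165% on average with vehicle and 0.0368% with T09, and the adipocyte and acinar lists each have 1 vehicle library far above the rest, at 0.0330% and 0.119%.

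Lists of epithelial and immune cells held few calls. No gene was called in the brush border (15 tested, median -0.20), goblet (12), Paneth (11), stem cell (12), tuft (9) or proliferation (20) list. Adjusted over the list alone, 4 brush border and 2 stem cell genes were lower and none of the others changed, and 12 of 15 brush border and all 12 goblet genes had a log2 fold change below 0. Enteroendocrine genes had 1 lower of 16, and T and NK cell (13, median -0.05), macrophage and dendritic cell (12, median 0.48), B and plasma cell (6, median 1.11) and endothelial genes (10, median 0.22) had none called. The ribosomal protein (80), nuclear oxidative phosphorylation (84), mitochondrially encoded (12), pancreatic acinar (6), erythroid (4), interferon (17), MHC class II (8), glycolysis (17), circadian (16) and unfolded protein (16) lists also held no called gene. Adjusted over the list alone, 1 gene each was lower of the enteroendocrine, macrophage, circadian and unfolded protein lists. Camera called 5 of these lists, which were lost with an estimated correlation: ribosomal protein (adjusted p = 0.712), goblet (adjusted p = 0.660), oxidative phosphorylation (adjusted p = 0.809), mitochondrial (adjusted p = 0.712) and brush border (adjusted p = 0.712). Median, mean and camera direction also differed in sign for retinoid metabolism (median 0.09, mean -0.02, higher), T and NK cell (median -0.05, mean 0.07, higher) and erythroid genes (median -0.15, mean -0.10, higher), none of them called. Leaving out each library in turn, these 3 medians lay on both sides of 0 (-0.03 to 0.18, -0.34 to 0.15 and -0.65 to 0.47), and that of the brush border between -0.27 and -0.13. Brunner gland and gastric genes had 2 tested members, too few for a set test. Shares of counts by exact permutation test did not pass for the acinar (p = 0.286), erythroid (p = 0.857), Brunner gland (p = 0.486), mitochondrial (p = 0.143) or B and plasma cell (p = 0.314) list.

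**Figure D3:**
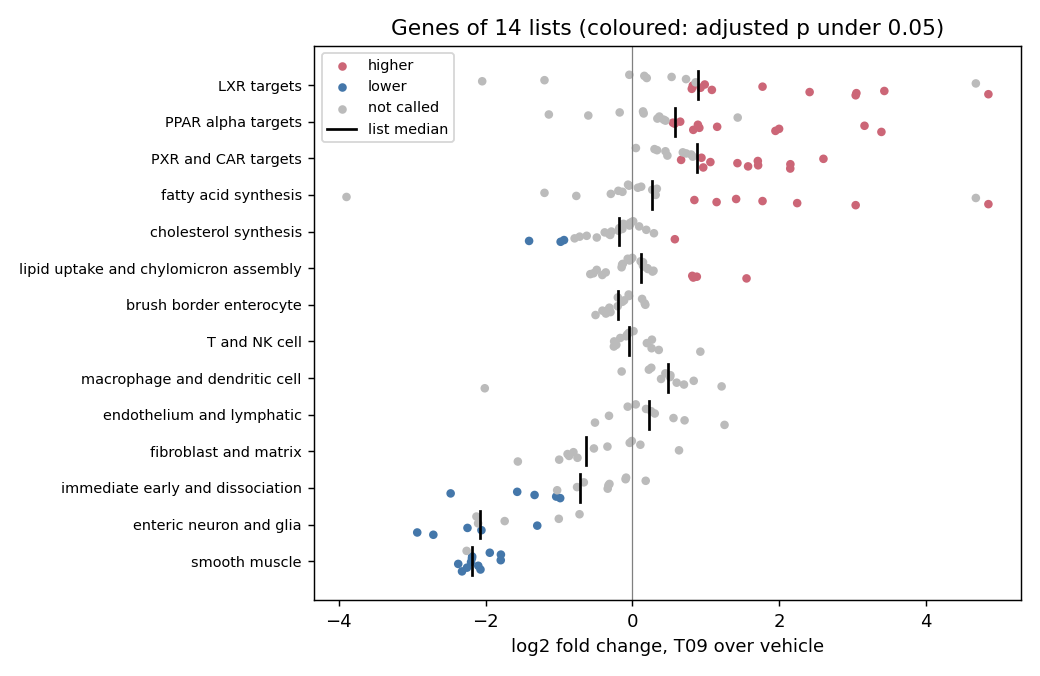
Log2 fold change (T09 over vehicle) of the tested genes of 14 lists, 1 point per gene, coloured where edgeR's adjusted p is under 0.05, with a line at each list's median. The median is 0.89 for LXR targets, -2.18 for smooth muscle and -0.20 for the brush border.

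Camera at its preset correlation called 18 of 35 lists, but other splits of the 7 libraries gave 8 to 23, so the number was not beyond that of other splits; with an estimated correlation 2 lists were called, against at most 1 in other splits. The count of 614 was 280 without vehicle replicate 3, 285 without vehicle replicate 4, 303 without T09 replicate 2, 251 without T09 replicate 3, 1091 with DESeq2, 179 against a 1.5-fold threshold and 0 with the smooth muscle score as a covariate (874 at an unadjusted p under 0.05), and the 409 lower genes were 258 without vehicle replicate 1. The score correlated with treatment at -0.94 across the libraries. The covariate fit therefore cannot separate muscle from treatment, and its count of 0 decides nothing.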

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

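In 106 sets of 4 vehicle values, 12 had a highest or lowest library whose gap to the nearest other, relative to the range, was above Dixon's critical value, where about 5.30 would be set apart by chance. The sets are not independent, as the adipocyte share and its genes Plin1, Adipoq, Car3 and Plin4 were flagged in the same library. Whether 12 exceeds chance is therefore uncertain. The share of the adipocyte list and the values of Scd1 and Fasn were looked at after the data were seen.

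Vehicle replicate 4 was the highest in 8 of them. It held 0.0330% of its counts in the adipocyte list (other vehicle libraries at most 0.00568%), 24.7 CPM of Plin1 (at most 2.16), 25.8 CPM of Adipoq (at most 1.97), 86.1 CPM of Car3 (at most 10.4) and 22.4 CPM of Plin4 (at most 6.62). It also held 503 CPM of Scd1 (at most 52.3), 257 CPM of Fasn (at most 60.6) and 3351 CPM of Vil1 (at most 3150.1). Vehicle replicate 1 was the highest for pancreatic acinar genes, at 0.119% of counts (0.00749% in vehicle replicate 2), and for the goblet gene Clca1, at 1092 CPM (others at most 744). Vehicle replicate 2 was the highest for Nos2, at 21.8 CPM (others at most 2.93), and the lowest for Nr1h2, at 111 CPM (others at least 132).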

How the results depend on the processing

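The smooth muscle covariate and the removal of both libraries numbered 1 were chosen after the data were seen. Scaling by size factors, by library size alone or without abundant genes, limma-voom, a stricter filter, no filter, a surrogate variable and the removal of both libraries numbered 1 left the counts of changed, higher and lower genes within 1.5 times of 614, 205 and 409. DESeq2 gave 1091 changed genes, 372 higher and 719 lower, and the cause was not tested. A test against 1.5-fold gave 179, 43 and 136, with 7 LXR targets higher, as a stricter hypothesis must. Leaving out 1 library gave 251 to 819 changed, 90 to 296 higher and 161 to 523 lower genes, with 10 to 12 LXR targets higher, 11 to 12 smooth muscle genes lower and 15 to 22 lists called. Of 57 named genes called, 45 stayed called whichever library was left out, and Abcc2, Fabp1, Fabp2, Reg3b, Il18, Insig1, Mvd, Stmn3, Gal, Fosb, Jun and Gclc lost the call without at least 1 (highest edgeR adjusted p from 0.0504 for Jun to 0.160 for Stmn3), with direction kept. Over all settings other than leaving out 1 library, named genes kept direction and side of the threshold in 997 comparisons, lost the call in 96, gained it in 41 and changed direction in 12; without 1 library these were 605, 49, 9 and 3. With an estimated correlation 2 lists were called and with fry 7. The 7 were LXR, PPAR alpha, PXR and CAR, fatty acid synthesis, smooth muscle, enteric neuron and immediate early genes.

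With the smooth muscle score as a covariate, 0 genes changed, 0 were higher and 0 lower, with 0 LXR targets and 0 smooth muscle genes called. The score differed between the groups (means 6.23 and 4.14 log2 CPM) and correlated with treatment at -0.94. The median SE of the 614 genes went from 0.26 to 0.65. As the score is also the mean of the smooth muscle genes themselves, the loss of their calls decides nothing. Of the 205 higher genes 203 stayed above 0, and of the 409 lower genes 333 stayed below 0. Named genes that changed sign there were Stmn3 (0.63), Gal (1.42), Nr1h2 (0.38), Abcc3 (-0.057), Nr5a2 (-0.078), Tpsg1 (0.36), Car3 (1.37), Plin4 (2.46), Plin1 (3.35), Adipoq (5.25) and Fasn (1.32), and none of these was called with the covariate; the cause was not tested beyond the overlap of score and treatment.

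Whether the replicate numbers pair the samples was not settled. Deviations from the group means correlated at 0.256, 0.0302 and -0.0270 across genes for numbers 1, 2 and 3. The value for number 1 was the highest between any vehicle and T09 library. Not every library correlated best with its own number: vehicle replicate 3 did so with T09 replicate 2 (0.0667). With the number as a block on 6 libraries, 280 genes changed, 113 higher and 167 lower, against 285, 103 and 182 on the same libraries with no replicate block, the fit without vehicle replicate 4. Fasn was 0.13 with the block and 0.034 without it.

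Leaving out 1 library turned the direction of results that were not called. The ranges were -0.74 to 0.059 for the log2 share of Brunner gland genes, -0.50 to 0.36 for erythroid genes, -2.13 to 0.29 for Akp3, -1.53 to 0.034 for Fasn and -0.10 to 0.0048 for Nr1h2. The smooth muscle share ranged from -2.40 to -1.90. Its exact permutation p was 0.1 without a vehicle and 0.0667 without a T09 library, each the smallest that 6 libraries allow. With all 7 the value adjusted over 6 lists, 0.171, did not pass either, but a single list at the smallest possible p cannot pass it. Without T09 replicate 1, 8 of 12 fibroblast and matrix genes were called lower, against 0 with all libraries. Across 7 libraries, the test on simulated counts found 48.8% of 2-fold changes, so smaller changes are often missed at this depth and number of mice.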

Other observations

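The tests of the muscle wall and of scaling were chosen after the result was seen, as were the genes Nqo1, Gclc, Akp3 and Ada, the count of splits per list and the list medians without each library. Of 20 targets of NRF2, the regulator of the oxidative stress response, 19 were tested and 5 were higher, among them Nqo1 (log2 fold change 1.05, SE 0.15) and Gclc (log2 fold change 0.94, SE 0.16, not called without vehicle replicate 3), and none lower. The alkaline phosphatase gene Akp3 varied within both groups, with 79710, 35217, 4025 and 3326 counts in the vehicle and 43270, 5771 and 6938 in the T09 libraries. Ada (adenosine deaminase) lay at 3206 ± 649 CPM with vehicle and 1309.9 ± 788 CPM with T09 (edgeR adjusted p 0.103).

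No other split of the 7 libraries into 4 and 3 gave a called gene. The real split, 1 of 35, had 614 changed, 205 higher and 409 lower genes and the highest other split 0 in each. A share of 1 in 35 (0.0286) is the smallest this design allows, so chance is made less likely but is not excluded. Every other split also mixes T09 and vehicle libraries within a group, which can widen its spread and lower its count. For the number of lists called by camera the real split did not stand out: 15 of the 35 splits called at least its 18, and the highest called 23. By list, the real split alone (1 of 35) gave the smallest camera p for LXR, PPAR alpha, PXR and CAR, smooth muscle, enteric neuron and lipid uptake genes. As small a p was reached in 2 splits for fatty acid synthesis, inflammation and immediate early genes, in 3 for bile acid handling, in 10 for cholesterol synthesis, 11 for the brush border, 12 for goblet, 15 for fibroblast and 15 for adipocyte genes, 16 for ribosomal protein, 16 for mitochondrial and 22 for nuclear oxidative phosphorylation genes, so chance is not excluded for these lists. Nor is chance excluded for the lists where the real split stood alone. There 1 in 35 is the smallest share possible, and it was not adjusted over the 35 lists tested.

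Smooth muscle and enteric neuron genes were among the lower genes, 11 of 12 and 5 of 10. Of 12 fibroblast and matrix genes 0 were called, but 8 without T09 replicate 1, so how far the decrease extends to connective tissue stays open. Scaling does not account for the lower smooth muscle genes, since the smooth muscle median stayed at -2.18 or lower under 3 other scalings. A loss of all cells other than enterocytes is also argued against: the lower of the T and NK cell and macrophage medians lay 2.14 above the smooth muscle median. Leaving out each library in turn gave 1.11 to 2.52, above the bound of 1 set in advance but close to it without T09 replicate 1. There the macrophage median fell to -0.77 and the T and NK cell median to -0.19, so a loss shared by some of these cells stays open. Less muscle wall in the T09 samples is a candidate explanation. All 12 smooth muscle genes were below 0, but that is the pattern to be explained. The other 398 lower genes followed the smooth muscle score within groups. Their median correlation lay 0.565 above that of all genes (exact permutation within groups, one-sided p = 0.00694, the smallest possible). Of them 50.8% had a within-group correlation above 0.5, against 17.3% of all genes, so not every lower gene followed the score. Whether less muscle wall would come from sampling or from T09 was not tested, as the lower smooth muscle share follows the treatment in all 7 libraries.

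A lower muscle share that raised every epithelial gene would have raised the brush border list, unless scaling removed the rise. Its median was -0.20 (-0.27 to -0.13 when each library was left out in turn), with 12 of 15 genes below 0. The brush border genes thus showed no rise after TMM scaling. That scaling would remove a rise shared by most genes (median log2 fold change of all genes tested 0.02). These values therefore cannot decide whether such a rise took place. The brush border median lay at -1.08 relative to that of the higher genes, but those were selected for being higher, so this gap decides nothing. For the xenobiotic enzymes, GC content and length are argued against as the cause, since 11 of 11 called PXR and CAR targets stayed called with that trend removed. An oxidative stress response cannot be told apart: the NRF2 list's camera p was 1.23e-05 (p = 0.0476 with an estimated correlation), but its median log2 fold change of 0.218 lay under the 0.3 set in advance. Both camera p of the NRF2 list are unadjusted, unlike those of the other lists. Whether T09 acts on the higher genes through LXR, PXR or another receptor stays open: it was not tested, and T09 given to mice lacking these receptors, not analysed here, would be the test.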
